A study of Homo sapiens with 4 samples.

How the data were processed

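Gene expression was measured in RKO cells, an established human colon carcinoma line. Per the labels, 2 samples received an empty Flag vector (control) and 2 received a vector for Flag-tagged HIPK2, and all 4 were harvested 24 h after transfection. Total RNA was labelled with biotin and hybridised to 1-colour Affymetrix whole-transcript arrays, 1 array per sample. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

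The deposited values are log2 expression values per probe set, and per the submitters' processing notes they were made with Partek and RMA. RMA corrects the background, normalizes the arrays to each other and summarises the probes of a probe set, so a shift shared by all genes would be removed before deposit. The versions of these programs, the background setting and the genome build are not given in the sources used here. The values were taken as deposited and were not normalized again in the main comparison.

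The table held 28869 probe sets with 0 missing values. In the platform annotation 19310 probe sets had 1 gene symbol, 1752 had several and 7807 had none. Of the 19310, 19279 matched an entry of the RefSeq gene table of assembly GRCh38.p14 by Entrez identifier, and 0 symbols needed updating. Probe sets with several symbols or none were left out of the gene comparisons. For the 685 genes with more than 1 probe set the probe set with the highest mean over the 4 arrays was used, which left 18377 genes. In 3 of these 685 genes probe sets passed the threshold in opposite directions.

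HIPK2 arrays were compared with control arrays by a linear model with moderated variances (lmFit and eBayes of limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the 18377 genes and a threshold of 0.05 on the adjusted p. Differences are log2 of HIPK2 minus control, given with the standard error of the model, and SDs are over the 2 arrays of a group. The number of arrays limits the precision: the median standard error was 0.11 and the median 95% interval reached 0.24 to either side of the log2 difference. An exact permutation test of 2 against 2 arrays cannot give a p below 0.333, so all p-values rest on the variance shared between genes.

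Before the data were examined, 22 pathway lists, 3 lists of markers of other cell types and 1 list of housekeeping genes were fixed. The pathway lists covered 547 measured genes and were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the 22 lists; 1 of these lists is not reported here. Each was tested again with an estimated correlation and with fry. With an estimated correlation camera takes its p from the residual degrees of freedom of the 4 arrays. These are so few that hardly any list could pass, so a call lost there does not show that correlation between genes explains it. The named genes were fixed by rule at the same time: HIPK2 and its paralogs, the 12 genes with the largest log2 difference in each direction among those past the threshold whose groups did not overlap, up to 4 members of each list with the largest moderated statistic, and ACTB, GAPDH and B2M. The rule named 120 genes, of which 89 passed the threshold. Genes named outside this rule are said to have been chosen after their values were seen.

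The fit was tested on simulated data for 18377 genes with 200 changed genes. Gene means were those of the HIPK2 against control comparison. Variances were drawn from the prior that the fit had estimated, with independent normal errors. The simulation thus meets the model's own assumptions and does not test whether these arrays do. The fit recovered 41.8% of genes changed by 0.5 on the log2 scale, 100% of those changed by 1 and 100% of those changed by 2. Of its 174 calls, 13 were false.

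Alternatives fixed at the start were a variance prior with a trend and robust fitting, leaving out the dimmest 40% or 60% of genes, subtracting array medians, quantile normalization, averaging the probe sets of a gene, testing all 28869 probe sets, other thresholds, a block for the codes in the array titles and leaving out each array. An intensity-dependent loess normalization was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.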

Results

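The series asked which genes HIPK2 modulates in colon cancer cells, with an eye to genes of tumor progression. HIPK2 is a nuclear serine/threonine kinase that acts on several transcription factors and corepressors, and overexpression stood in for its activation. RKO cells were transfected with an empty Flag vector or with a HIPK2-Flag vector, with 2 arrays in each group. The 4 arrays had similar distributions, with medians between 4.17 and 4.21 log2 units. Over all 28869 probe sets the 2 control arrays correlated at r = 0.995 and the 2 HIPK2 arrays at r = 0.994, against 0.985 to 0.987 between groups; these are correlations across probe sets, which are not independent replicates.

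HIPK2 itself (probe set 8143307) was strongly raised in the cells given its vector. Its level was 6.93 ± 0.17 log2 units (SD, n = 2) in control arrays and 10.2 ± 0.57 in HIPK2 arrays, a log2 difference of 3.30 (SE 0.20) or 9.86-fold, with a limma adjusted p of 6.28e-06. Both HIPK2 arrays (9.83 and 10.6) lay above both control arrays (6.81 and 7.05). The array does not tell vector transcripts from those of the cells' own gene. Its paralogs did not pass the test: the log2 difference was 0.05 for HIPK1 (adjusted p = 0.888), 0.34 for HIPK3 (adjusted p = 0.11) and 0.04 for HIPK4 (adjusted p = 0.9). HIPK3 passed when control replicate 2 was left out, with a log2 difference of 0.53 and an adjusted p of 0.015, and with the array code as a block (adjusted p = 0.0404).

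**Figure D1:**
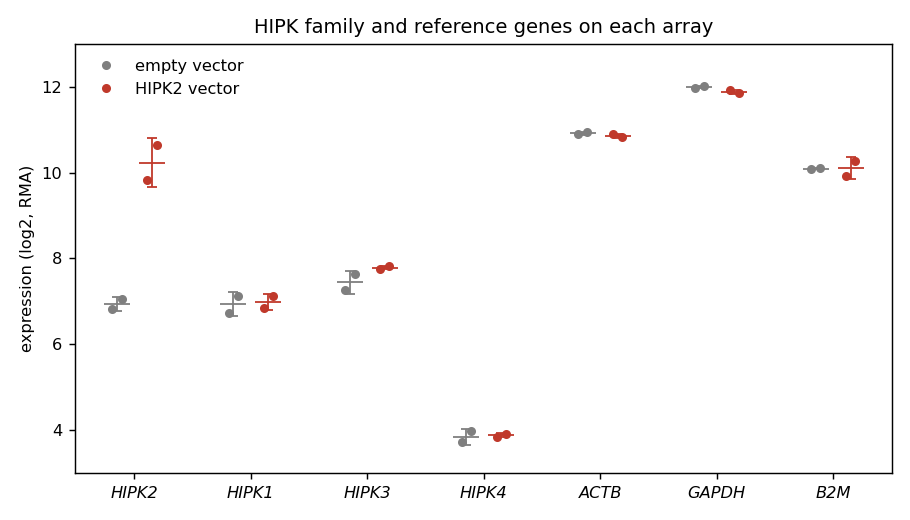
Log2 RMA expression of the HIPK family and of 3 reference genes on each array; points are arrays, horizontal marks are group means and bars are SDs (n = 2), in grey for the empty vector and red for the HIPK2 vector. HIPK2 sits at 9.83 and 10.6 in the HIPK2 arrays against 6.81 and 7.05 in the control arrays, while ACTB, GAPDH and B2M differ by -0.06, -0.12 and 0.01.

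Across the genome the largest falls included DDIT4, CHAC1 and CTH of the list of integrated stress and unfolded protein response genes, and the largest rises after HIPK2 included SLC30A1, MT1M and MT1B of the zinc response and HMGCS1, DHCR7 and EBP of cholesterol synthesis. Of 18377 genes, 1241 rose and 1688 fell in HIPK2 cells. Among them 48 rose and 72 fell by at least 2-fold, and the smallest log2 difference that passed was 0.33. After HIPK2, the largest rises were in SLC30A1, the zinc exporter of the plasma membrane (2.18, SE 0.12), EGR1, an immediate early transcription factor (2.11, SE 0.15), HMGCS1, an early enzyme of the mevalonate pathway (1.69, SE 0.11), TFRC, the transferrin receptor (1.66, SE 0.10), MT1M, a metallothionein (1.56, SE 0.11), and SCD, the stearoyl-CoA desaturase (1.54, SE 0.10). Further rises included SLC2A6 (1.47), a glucose transporter family member, and TAP1 (1.41), a peptide transporter of antigen presentation. The largest falls were in DDIT4, an inhibitor of mTORC1 signalling (-3.44, SE 0.11, adjusted p = 3.66e-08), CHAC1, which degrades glutathione (-3.40, SE 0.12, adjusted p = 6.34e-08), LURAP1L (-2.78, SE 0.12), CTH, the cystathionine gamma-lyase of cysteine synthesis (-2.63, SE 0.11), and TXNIP, a thioredoxin inhibitor induced by glucose (-2.56, SE 0.10). GRB10, an adaptor that restrains insulin signalling, fell by 1.83 on the log2 scale, TUBE1 by 1.72 and PDCD4, a translation inhibitor, by 1.66. All 2929 genes past the threshold had groups that did not overlap, as did 52.3% of all tested genes, where chance alone gives 33.3%.

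**Figure D2:**
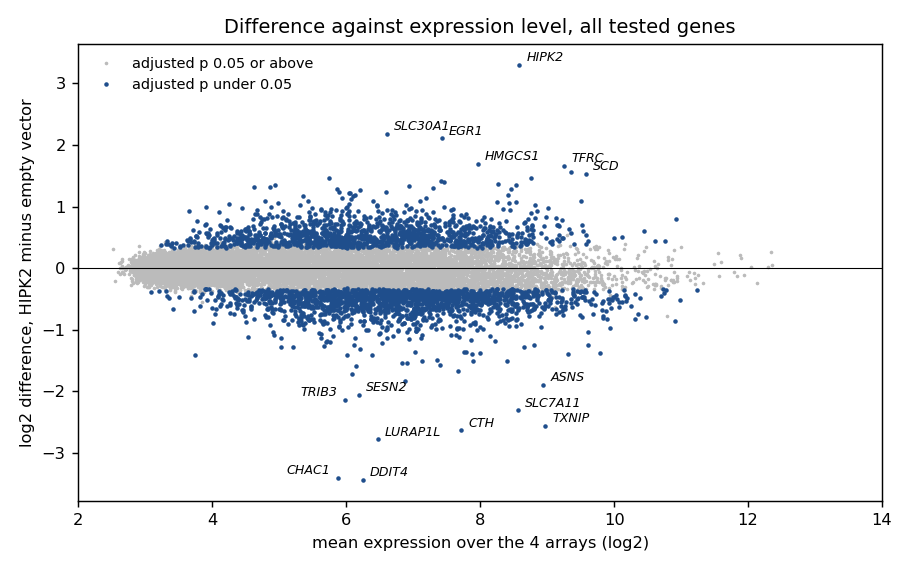
Log2 difference of HIPK2 minus empty vector (vertical axis) against the mean log2 expression over the 4 arrays (horizontal axis) for 18377 genes; each point is a gene, blue where the adjusted p was under 0.05. HIPK2 lies highest at 3.30 and DDIT4 lowest at -3.44.

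Genes of the integrated stress and unfolded protein response split, with the larger part lower. Of 31 measured members of this list 15 fell, 5 rose and 11 did not pass, and adjusted over the list alone 17 fell and 7 rose. Besides DDIT4, CHAC1 and CTH, the fall included SLC7A11, the cystine importer (-2.31, SE 0.10, adjusted p = 3.37e-07), TRIB3, a pseudokinase (-2.13, SE 0.12, adjusted p = 3.26e-06), and ASNS, the asparagine synthetase (-1.89, SE 0.11, adjusted p = 3.26e-06). The 5 members that rose were CALR (0.70), MANF (0.66), PDIA4 (0.57), HSP90B1 (0.43) and CRELD2 (0.38), all chaperones or folding factors of the endoplasmic reticulum, named after their values were seen. The unfolded protein response did not rise as a whole. Its members XBP1 (-1.18) and HERPUD1 (-1.36) fell, and HSPA5 (0.14), PDIA6 (0.34), SDF2L1 (0.35), SEL1L (0.29) and DNAJB9 (-0.19) did not pass, also named afterwards. ATF4, the transcription factor that drives many of the fallen genes, differed by -0.17 and did not pass, nor did ATF3 (0.14), PPP1R15A (-0.25), SLC7A5 (-0.24) and NUPR1 (-0.29), all also named afterwards. The list median was -0.29, and camera called the list lower (adjusted p = 1.48e-06). With an estimated correlation the call was lost (adjusted p = 0.446). The state of the cultures and the vector cannot be separated with these arrays.

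Genes of the cholesterol synthesis list, not all of them enzymes, rose almost throughout. Of 20 measured members 17 rose, 0 fell and 3 did not pass, and adjusted over the list alone 17 rose. HMGCS1 rose 3.24-fold, DHCR7, which catalyses the last step to cholesterol, 2.76-fold (log2 difference 1.46, SE 0.11, adjusted p = 1.99e-05), EBP, a sterol isomerase, 2.57-fold (1.36, SE 0.13, adjusted p = 0.000112) and LSS, the lanosterol synthase, 2.51-fold (1.33, SE 0.11, adjusted p = 3.13e-05). The list median was 0.79 (camera adjusted p = 8.24e-19). With an estimated correlation the adjusted p was 0.44.

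SLC30A1 and some metallothioneins, which answer to free zinc, rose as well. In this list of 11 measured genes 5 rose, 1 fell and 5 did not pass, and adjusted over the list alone 5 rose and 2 fell. SLC30A1 went from 5.52 ± 0.17 to 7.70 ± 0.10 log2 units (SD, n = 2), MT1M from 8.57 ± 0.12 to 10.1 ± 0.098, MT1F from 7.86 ± 0.087 to 9.21 ± 0.25 and MT1B from 6.70 ± 0.019 to 8.12 ± 0.46. The metallothioneins MT2A (0.16), MT1E (0.23), MT1G (0.24) and MT1H (0.17), named after their values were seen, did not pass. Metallothionein transcripts are near-identical copies of each other, so the assignment to single members is uncertain. The list median was 0.25 (camera adjusted p = 3.08e-05), with an adjusted p of 0.446 with an estimated correlation.

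**Figure D3:**
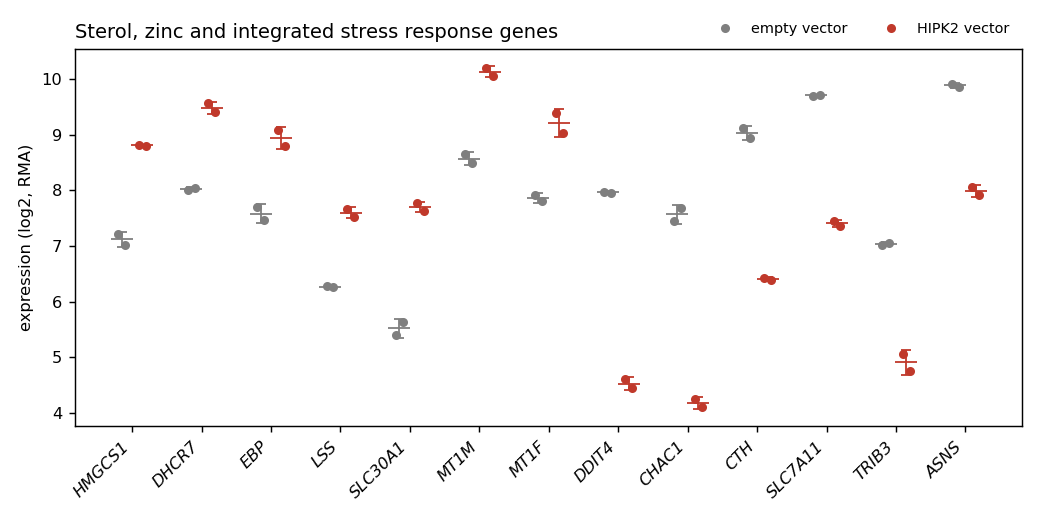
Log2 RMA expression of 4 sterol, 3 zinc and 6 integrated stress response genes on each array; points are arrays, horizontal marks are group means and bars are SDs (n = 2), in grey for the empty vector and red for the HIPK2 vector. The groups do not overlap for any gene shown, from SLC30A1 at a difference of 2.18 to DDIT4 at -3.44.

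Genes of mitosis and DNA replication fell in HIPK2 cells. Among 31 mitosis genes 19 fell, 1 rose and 11 did not pass, with a median of -0.38. Adjusted over the list alone 23 fell and 1 rose. After quantile and loess normalization 15 and 14 fell, with medians of -0.364 and -0.33. NUSAP1, a spindle-associated protein, fell by 1.08 on the log2 scale (SE 0.10, adjusted p = 0.00012), NEK2, a centrosomal kinase, by 0.99 (SE 0.13), CDK1, the mitotic cyclin-dependent kinase, by 0.77 (SE 0.11) and KIF20A by 0.67 (SE 0.11). The member that rose was MKI67 (0.42), named after its value was seen. Among 37 DNA replication genes 13 fell, 0 rose and 24 did not pass, with a median of -0.26, and adjusted over the list alone 16 fell and 1 rose; after loess normalization the median was -0.16 and 11 fell. MCM2, a subunit of the replicative helicase, differed by -0.86 (SE 0.11), RFC4 by -0.81 (SE 0.10), TK1 by -0.79 (SE 0.12) and PRIM1 by -0.72 (SE 0.10). Of 19 replication-dependent histone genes 8 fell and 3 rose, and adjusted over the list alone 10 fell and 3 rose; H1-2 differed by -0.91, H1-4 by -0.86 and H4C8 by 0.82, and these genes have close copies that may share probes. Camera called all 3 lists lower, with adjusted p of 1.3e-10 for mitosis, 1.93e-06 for DNA replication and 0.00205 for histones. With an estimated correlation none passed (adjusted p = 0.44, 0.446 and 0.44), and the histone call was lost without the dimmest 60% of genes (adjusted p = 0.0644).

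Subunits of the respiratory chain fell as well. Of 31 oxidative phosphorylation genes 15 fell, 1 rose and 15 did not pass, with a median of -0.40, and adjusted over the list alone 19 fell and 1 rose. NDUFS7 of complex I differed by -0.65 (SE 0.10, adjusted p = 0.00187) and COX5B of complex IV by -0.60 (SE 0.12, adjusted p = 0.0052), while UQCRB of complex III rose by 0.61 (SE 0.11, adjusted p = 0.00349). SDHD was among the fallen genes (-0.67, adjusted p = 0.00453), but its probe set may read a pseudogene, which was not checked. Among 26 cytosolic ribosomal protein genes 5 fell, 0 rose and 21 did not pass, with a median of -0.26, and adjusted over the list alone 7 fell. RPL13 showed the clearest fall (-0.65, SE 0.10, adjusted p = 0.0018). Ribosomal protein genes have many near-identical pseudogenes that may share their probes, and RPS15 (-0.60, adjusted p = 0.00446) did not pass with the mean of its probe sets (-0.24, adjusted p = 0.176). Both lists were called lower by camera (adjusted p = 1.02e-06 and 0.000316), and with an estimated correlation both had an adjusted p of 0.44. Among all tested genes the median log2 difference also fell with expression level, and was -0.13 in the brightest decile, which began at 7.82 log2 units; the median levels of the lists were 7.92 and 9.62. After loess normalization, chosen once that trend had been seen, the ribosomal list no longer passed (adjusted p = 0.114), its median was -0.12 and 2 members fell, while 8 oxidative phosphorylation genes fell and that list still passed (adjusted p = 8.75e-05).

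Of 27 genes of the apoptosis machinery 5 fell, 1 rose and 21 did not pass, and adjusted over the list alone 6 fell and 1 rose. BCL2A1, an antiapoptotic BCL2 relative, fell by 1.12 on the log2 scale (SE 0.10, adjusted p = 0.000106), CASP6, an executioner caspase, by 0.59 (SE 0.10, adjusted p = 0.00284) and TRADD, an adaptor of the TNF receptor, by 0.51 (SE 0.10, adjusted p = 0.0066), so the fallen members act on both sides of cell death. The median was -0.24 and camera called the list lower (adjusted p = 0.0195), with an adjusted p of 0.446 with an estimated correlation. The call did not hold without control replicate 1 (median -0.14, adjusted p = 0.0503), without HIPK2 replicate 2 (median -0.10, adjusted p = 0.105), or without the dimmest 40% (adjusted p = 0.0915) or 60% of genes (adjusted p = 0.333). Among 30 partners and regulators of HIPK2, 3 rose, 3 fell and 24 did not pass (camera adjusted p = 0.757), and adjusted over the list alone 3 rose and 4 fell. The acetyltransferases EP300 (0.85, SE 0.11, adjusted p = 0.000707) and CREBBP (0.73, SE 0.16, adjusted p = 0.00968) rose, and the deacetylase HDAC1 (-0.52, SE 0.11, adjusted p = 0.0079) and catalase, CAT (-0.83, SE 0.11, adjusted p = 0.000629), fell.

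Among genes tied to tumor progression the changes differed between lists. The invasion, epithelial, mesenchymal and Wnt lists were dim, with median levels of 3.82, 3.56, 3.87 and 4.07, below 4.63 for all tested genes. Of 1838 tested genes at 3.66 to 3.99 log2 units, 31 rose and 14 fell. A lack of calls in these 4 lists may therefore reflect low expression and does not show that HIPK2 left them unchanged. None of 29 invasion and angiogenesis factors passed the limma test at an adjusted p of 0.05, over all genes or adjusted over the list alone (median 0.04, camera adjusted p = 0.281), and 2 had an unadjusted p under 0.05; ADAM10 differed by 0.35 (adjusted p = 0.0645) and PLAU by 0.40 (adjusted p = 0.105). ADAM10 passed after quantile (adjusted p = 0.0204) and loess normalization (adjusted p = 0.0166), with the array code as a block (adjusted p = 0.0253) and without control replicate 1 (adjusted p = 0.0463). PLAU passed without control replicate 2 (adjusted p = 0.0184) or HIPK2 replicate 2 (adjusted p = 0.0104). Of 32 hypoxia and HIF-1 target genes 9 fell and 3 rose, and adjusted over the list alone 9 fell and 5 rose (median -0.02, camera adjusted p = 0.403); 6 rose after loess normalization or with the array code as a block. VEGFA, the angiogenic growth factor, fell by 0.95 (SE 0.10, adjusted p = 0.000262), PDK1, a mitochondrial kinase, by 0.86 (SE 0.11, adjusted p = 0.000551), NDRG1 by 0.71 (SE 0.11) and PGK1, a glycolytic enzyme, by 0.69 (SE 0.11). Of 20 Wnt and beta-catenin targets 2 fell and 0 rose (camera adjusted p = 0.75), and adjusted over the list alone 1 fell. After loess normalization 2 rose and 2 fell, as CCND1 (0.32, adjusted p = 0.0799 as deposited and 0.0468 after loess) and CD44 (0.24, adjusted p = 0.146 and 0.0443) passed there, and with the array code as a block 1 rose. MYC fell by 0.76 (SE 0.11, adjusted p = 0.00111), while BMP4, near background at 3.91, differed by -0.34 (adjusted p = 0.0477) and lost its call when any of the 4 arrays was left out. The median of this list was 0.01, its mean -0.01, and camera's direction was up. Of 16 mesenchymal genes ACTA2 rose (0.71, SE 0.10) and ZEB1 (-0.54, SE 0.11) and VIM (-0.42, SE 0.11) fell; VIM, near background at 3.85, lost its call without control replicate 2 (adjusted p = 0.194) or HIPK2 replicate 2 (adjusted p = 0.0753). The counts adjusted over the list alone were the same (camera adjusted p = 0.634). Of 19 epithelial and colonocyte genes KRT18 (-0.84, SE 0.12) and CA2 (-0.42, SE 0.10) fell, with the same counts adjusted over the list alone; camera did not call this list (adjusted p = 0.403), while fry called it lower (adjusted p = 0.0298) at a median of -0.06. KRT18 has many near-identical pseudogenes that may share its probes, and CA2 lost its call without control replicate 1 (adjusted p = 0.0763). Of 18 YAP and TEAD targets 2 rose and 1 fell, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.403); FJX1 rose by 0.63 (SE 0.10) and CCN2 fell by 0.51 (SE 0.10).

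Immediate early genes split into opposite directions. Of 24 genes 3 rose, 7 fell and 14 did not pass, and adjusted over the list alone 3 rose and 8 fell (median -0.15, camera adjusted p = 0.259). Besides EGR1, the AP-1 subunits FOS (1.31, SE 0.15, adjusted p = 0.000319) and FOSB (0.88, SE 0.10, adjusted p = 0.000355) rose, while DUSP1, a phosphatase that switches off MAP kinases, fell (-1.02, SE 0.11, adjusted p = 0.000252). Of 22 NF-kB targets and cytokines 2 rose and 2 fell, with the same counts adjusted over the list alone; after quantile normalization 3 rose and 0 fell. TNFAIP3, a feedback inhibitor of NF-kB, rose 2.48-fold (1.31, SE 0.11, adjusted p = 4.09e-05) and ICAM1, an adhesion molecule, 1.4-fold (0.49, SE 0.10, adjusted p = 0.0084). The list median was 0.11 and camera called it higher (adjusted p = 0.0195), with an adjusted p of 0.446 with an estimated correlation. That call was lost without control replicate 1 (median 0.04, adjusted p = 0.14), without HIPK2 replicate 1 (median 0.09, adjusted p = 0.0568), and without the dimmest 40% (adjusted p = 0.0541) or 60% of genes (adjusted p = 0.771). Of 33 interferon-stimulated genes 2 fell and 0 rose, as also adjusted over the list alone (camera adjusted p = 0.297); IFI27 fell by 0.56 (SE 0.11, adjusted p = 0.00491). After quantile or loess normalization 1 of them rose, and with the array code as a block 3 did, among them MX1 (0.33, adjusted p = 0.0507 as deposited and 0.0349 with the block). Of 18 heat shock protein genes 3 rose and 1 fell, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.403), led by HSPH1 (0.70, SE 0.10, adjusted p = 0.00129). The median of this list was -0.01, its mean 0.05 and camera's direction up. After loess normalization it passed as higher, with an adjusted p of 0.0497 and 5 genes that rose, against 1 with array medians subtracted. Of 22 NRF2 antioxidant genes 1 rose and 3 fell, and adjusted over the list alone 1 rose and 4 fell (camera adjusted p = 0.75). After quantile normalization 1 rose and 1 fell. OSGIN1 rose by 0.53 (SE 0.11, adjusted p = 0.00739). NQO1 (-0.43, adjusted p = 0.0145), TXNRD1 (-0.51, adjusted p = 0.0243) and TALDO1 (-0.43, adjusted p = 0.0295) fell, and each of these 3 lost its call under some alternative.

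**Figure D4:**
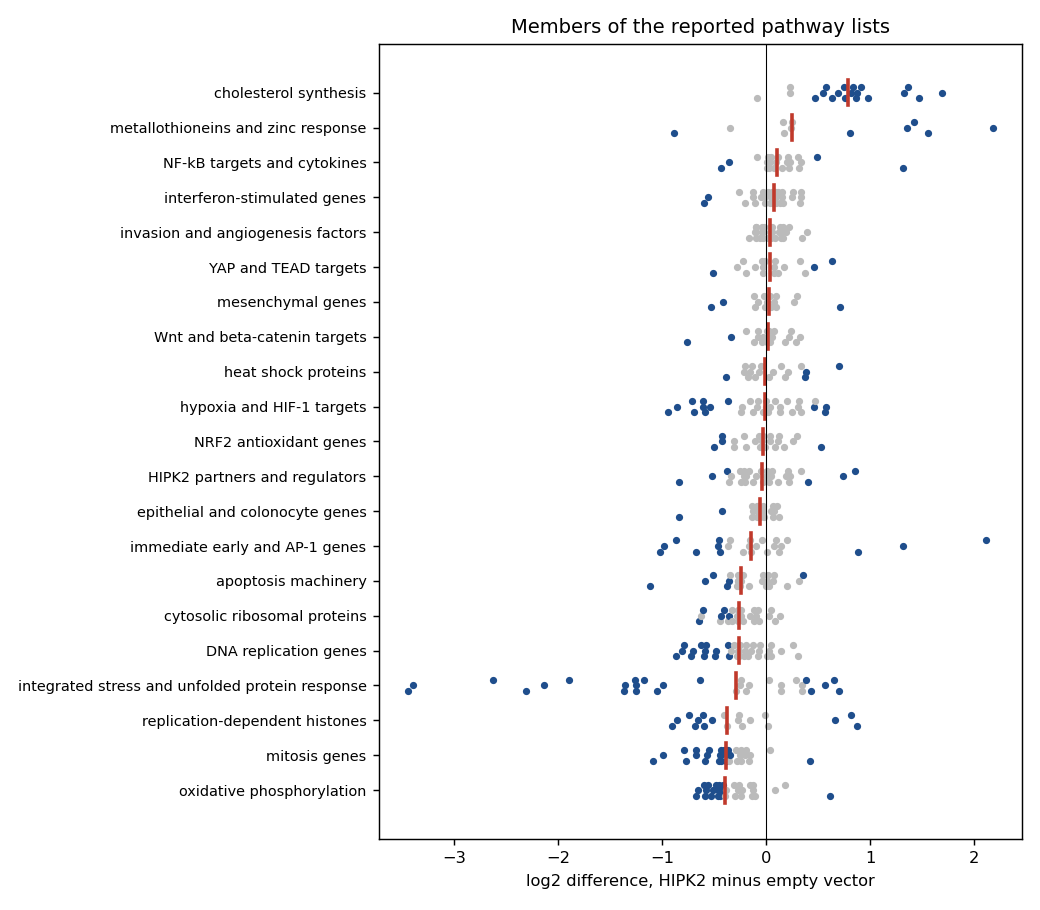
Log2 difference of HIPK2 minus empty vector for the measured members of the reported pathway lists; each point is a gene, blue where its adjusted p over all genes was under 0.05, and each red bar is the list median. Medians run from -0.40 for oxidative phosphorylation to 0.79 for cholesterol synthesis.

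Markers of other cell types stayed near background. None of 12 fibroblast, 13 leukocyte and 10 endothelial markers passed the limma test at an adjusted p of 0.05 (0, 0 and 1 at an unadjusted p under 0.05), and their median levels were 3.41, 3.53 and 3.35 log2 units, below the median of 4.63 over all tested genes. Of 9 housekeeping genes HPRT1 (-0.58, SE 0.10, adjusted p = 0.00316) and PGK1 fell, and 7 did not pass. ACTB differed by -0.06 (SE 0.10), GAPDH by -0.12 (SE 0.10) and B2M by 0.01 (SE 0.13). The median of the housekeeping list was -0.12 and turned to 0.05 after quantile or loess normalization.

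In all, camera with its preset correlation called 4 of the 22 pathway lists higher and 7 lower. With an estimated correlation 0 lists passed, with 1 list at an unadjusted p under 0.05. Given the few residual degrees of freedom, that outcome was nearly fixed in advance, and no conclusion is drawn from it.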

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

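Probe sets outside the gene comparisons also differed between the groups, and they were flagged because no comparison above uses them. With all 28869 probe sets tested, 313 without a gene symbol rose and 196 fell in HIPK2 cells. Among probe sets with several gene symbols 93 rose and 90 fell. These shares were 6.52% of the unnamed and 10.4% of the several-symbol probe sets, against 12.7% of those with 1 symbol.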

How the results depend on the processing

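Loess normalization was chosen after the data were seen. HIPK2 passed under every alternative run, at log2 differences of 2.90 to 3.71, both from leaving out an array. Of the 89 named genes past the threshold, 72 passed in the same direction under every alternative that tested them, as the filters on dim genes left some out; none reversed while called. The number of genes that rose was 459 with a further 1.5-fold minimum and 2119 at an unadjusted p under 0.05, and the number that fell was 600 and 2796; these follow from the thresholds. Leaving out each array in turn gave 964 to 1123 genes that rose, 1172 to 1778 that fell and 9 to 10 lists; each of these fits compared 1 array with 2, with the spread from 1 group only, so they are weak evidence of stability. The share of calls that rose was 42.4% as deposited, 36.1% with array medians subtracted, 48.6% after quantile and 50.9% after loess normalization. Of the 11 lists called, 7 were called without the dimmest 60% of genes, where fewer genes were tested. With an estimated correlation 0 of the 22 lists passed. Fry called 5, of which 4 were among these 11 and the other was the epithelial and colonocyte list. Fry asks another question, whether members differ from no change, while camera sets members against the other genes. For the histone and cytosolic ribosomal lists the estimated correlation was -0.053 and -0.0083, below the preset 0.01. A higher correlation was therefore not what lost these calls with an estimated correlation. That form of camera uses only the few residual degrees of freedom of the 4 arrays, which by itself raises the p-values. The lost calls thus say little about correlation between genes. The array titles carry codes of unstated meaning. With code pairs as a block 1603 genes rose and 2127 fell, and all 2929 calls were kept; within-group differences of like-coded arrays correlated at 0.121 across genes and at 0.214 across genes above the median level, and whether the codes pair the arrays stays open. The medians of the Wnt, hypoxia, mesenchymal and heat shock lists, none of them called as deposited, changed sign under some scalings. Few dim genes passed: in the dimmest decile 1 gene rose and 2 fell. Whether detection is limited there was not tested.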

Other observations

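The gene groups in this part were put together after the values were seen. Apart from an undecided test of host transcripts, the tests of explanations in it were written after the values they bear on had been seen. In all 10 groups were tested, and their p-values are adjusted over these 10. The limit given above for camera with an estimated correlation holds for these groups too. The enzymes that charge tRNAs were lower. Of 17 cytosolic aminoacyl-tRNA synthetases 12 fell and 0 rose, with a median of -0.68 (camera adjusted p = 1.63e-11, and adjusted p = 0.191 with an estimated correlation). CARS1 and AARS1 both differed by -1.39 (SE 0.11), SARS1 by -0.97 (SE 0.13) and GARS1 by -0.83 (SE 0.11). Mitochondrial ribosomal proteins were lower too: 26 of 74 fell and 1 rose, with a median of -0.27 (camera adjusted p = 3.27e-09, and adjusted p = 0.191 with an estimated correlation), MRPL13 among them at -0.84 (SE 0.11). After loess normalization 14 of these fell and 2 rose.

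Lysosomal genes and fatty acid synthesis genes were higher. Of 31 lysosomal hydrolases and membrane proteins 13 rose and 0 fell, with a median of 0.27 (camera adjusted p = 1.92e-08, and adjusted p = 0.212 with an estimated correlation); NEU1, a sialidase, rose by 1.02 (SE 0.11), TPP1, a peptidase, by 0.92 (SE 0.10) and LIPA, which splits cholesteryl esters, by 0.82 (SE 0.14). Of 15 fatty acid synthesis genes 5 rose and 0 fell (camera adjusted p = 3.46e-05, and adjusted p = 0.191 with an estimated correlation), among them SCD and FASN, the fatty acid synthase (1.08, SE 0.16). Of 387 solute carriers 82 rose and 12 fell, with a median of 0.04 (camera adjusted p = 1.6e-05, and adjusted p = 0.191 with an estimated correlation); SLC15A3, SLC5A6 and SLC36A1 rose by 1.24, 1.19 and 0.96, and SLC7A11 fell by 2.31. Small nucleolar RNAs, which guide the modification of ribosomal RNA, were higher as a class: 73 of 175 rose and 1 fell, with a median of 0.29 (camera adjusted p = 1.01e-17, and adjusted p = 0.191 with an estimated correlation). SNORD78 differed by 1.09 (SE 0.12) and SNORA74A by 1.09 (SE 0.10), and some members have close copies that may share probes. The median of each group named so far in this part kept its sign with array medians subtracted and after quantile and loess normalization. Of the other 4 groups, 8 of 37 proteasome subunits fell and 0 rose (camera adjusted p = 0.000782, and adjusted p = 0.359 with an estimated correlation; 3 fell after loess normalization). Other small RNAs passed camera as higher at a median of 0.05 (adjusted p = 0.0216, and adjusted p = 0.439 with an estimated correlation), and vacuolar ATPase subunits (adjusted p = 0.249) and ZNF genes (adjusted p = 0.143) did not pass.

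The first pattern weighed is the fall of 15 integrated stress and unfolded protein response genes. A level-dependent difference between the arrays is argued against by its size. The median over all genes was -0.126 in the brightest decile, against -1.36 for the 15 fallen members. After loess normalization 15 of the 15 still passed as lower, with a median of -1.25. That count adds little, since so small a correction could hardly undo falls picked for passing. Exhausted medium in the control cultures stays open: it might also raise hypoxia genes in controls, but the hypoxia list passed in neither direction (adjusted p = 0.403), and culture state and vector cannot be told apart in this design. An effect of HIPK2 on these genes is a hypothesis that these arrays do not separate from it.

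The second pattern is the lower median of oxidative phosphorylation and cytosolic ribosomal protein genes, of which 15 of 31 and 5 of 26 passed as lower. For oxidative phosphorylation, the median of -0.398 lay outside the central 95% of 10000 random lists matched on level (-0.23 to 0.06). It also lay outside that of lists matched on level and gene span (-0.28 to 0.01). These ranges treat genes as independent, while the estimated correlation between members was 0.11, so they are too narrow. They argue only weakly against both trends as the whole cause. For ribosomal proteins, the median of -0.259 lay at the edge of the level-matched range (-0.26 to 0.02), so a level-dependent difference cannot be told apart from a change of these genes. Matched on level and gene span, random lists had a median of -0.19 (-0.34 to -0.02), which is consistent with a shared trend among short, bright genes. A biological change of the respiratory genes remains a hypothesis.

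The third pattern is the rise of small nucleolar RNAs, for which random lists matched on level centred on -0.02 (-0.06 to 0.02), against the median of 0.289, which argues against the level trend. A rise of all small RNAs alike is argued against by 36 other small RNAs above the median level. Their median was 0.0556, against 0.486 for 101 small nucleolar RNAs at such levels (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). These resamples treat RNAs and not preparations as replicates, and the sets were not matched on level beyond that cut. As whole classes, other small RNAs were dimmer, with a median level of 3.76 against 5.44 for small nucleolar RNAs. The whole class of other small RNAs also passed camera as higher (adjusted p = 0.0216). More small RNA of some classes in the HIPK2 preparations therefore stays open. Higher host transcripts are argued against as the main cause for the 45 of the 73 with a measured host. Their 35 hosts, assigned by position without strand, had a median of -0.0328 (bootstrap 95% interval -0.172 to 0.0436), with 4 that rose and 3 that fell. Over all small nucleolar RNAs with a measured host, called or not, the median per host was 0.413. The 63 hosts of that wider set had a median of -0.0328 (-0.103 to 0.0436). Some hosts, such as RPL27A and RPS3, are ribosomal protein genes, whose values a level-dependent difference may have lowered. For the other 28 of the 73 no host was measured by a probe set with 1 symbol, so a rise carried by the host stays open for them. An earlier host test, written before its values were seen, covered all 73. It was left undecided, since 61.6% had a measured host against a minimum of 80%. An effect of HIPK2 on small nucleolar RNAs is a hypothesis.

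Of the 3 ways to split the 4 arrays into pairs, 1 gave as many genes past the threshold, the real one, with 2929. The highest other split gave 0 by limma, with 220 and 103 genes at an unadjusted p under 0.05 in the other splits against 4915. Each other split puts 1 HIPK2 and 1 control array in each group, so the real difference counts as spread there. Low counts were thus fixed in advance, and these splits are no null for the real one. With 3 splits no share under 0.05 can be reached.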
